A study of Homo sapiens with 11 samples.

How the data were processed

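Poly(A) RNA of 3 human mammary cell lines was measured by sequencing with the TruSeq Stranded mRNA library kit, in 4 libraries of HCC1937, 4 of MDA-MB-231 and 3 of MCF10A. Per the labels, the authors trimmed the reads with Trimmomatic 0.39, aligned them to GRCh38 with STAR 2.7.1a and counted them with featureCounts 2.0.0. Per the file headers, the deposited values are raw counts per gene over the exons of Ensembl release 99, with no normalisation, 1 file per library. The headers show the option for read pairs and no option for strand, multiply mapped reads or overlapping genes. Reads were therefore counted without regard to strand, reads in overlapping genes were left out, and near-identical relatives (keratins, HLA, kallikreins, cystatins, histones, cancer/testis families) lost the reads they share. The headers also name the aligned input as unpaired trimmed reads, so whether the counts are of pairs or of single reads is not known.

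The files hold 60617 genes, of which 60357 IDs matched a symbol in the annotation, with 1194 duplicate symbols. Each library was tied to its line and replicate number through its label. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (1.17.8). Genes were filtered with filterByExpr by line, which left 17939, and libraries were scaled with TMM. All 11 libraries were fitted in 1 quasi-likelihood model with the line as its only factor, and each pair of lines was tested two-sided in it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of 1 or more. SE is that of the log2 fold change, taken as its size over the square root of F. Folds are ratios of mean CPM. Total counts run from 17859926 to 39227505 per library. Where a line had 0 counts over all its libraries the fold is a bound at 3 counts over the line, and where it had 1 to 3 counts a 95% counting interval is given.

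The tests, thresholds, gene lists, rule for named genes and alternatives were fixed before the data were examined. The 30 lists hold 776 gene names, of which 774 matched. They cover basal and myoepithelial, luminal, epithelial junction and mesenchymal genes, collagens, pericellular proteases, interferon response, antigen presentation, cytokines and chemokines, cell cycle, homologous recombination, p53 targets, DNA methylation genes, histone modifiers, cancer/testis genes, epidermal differentiation, EGFR ligands and targets, glucocorticoid response, cAMP response, cholesterol, fatty acids, glycolysis and hypoxia, NRF2 targets, loci often reported as deleted, leukocyte and endothelial markers, fibroblast markers, ribosomal proteins, mitochondrially encoded mRNAs, replication-dependent histones and stress response. Lists with 5 or more tested members were tested with camera, which compares a list's genes with all others, at a preset correlation of 0.01 and also with an estimated correlation, and with fry, which tests whether a list's genes move 1 way on balance. A list was called at an adjusted p under 0.05 over the lists of a comparison.

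Named genes are the 10 with the largest and the 10 with the smallest log2 ratio of mean CPM + 1 among called genes with a symbol, 10 CPM or more in the higher line and CPM ranges that do not overlap. Up to 4 called members per list, the 10 highest and 10 lowest genes in both tumour lines, and 30 genes set beforehand were added. Values of part of these are printed, with the remaining ones in the counts. The results of some of these genes and of some silent segments are not reported here. Genes in silent chromosome segments and the epithelial genes of MCF10A replicate 1 were chosen after their values were seen.

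The alternatives were DESeq2, limma-voom, RLE, upper-quartile and library-total scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, only the compared lines fitted, removal of mitochondrially encoded genes, no fold minimum, a log2 minimum of 2, a test against a log2 change of 1, an adjusted p under 0.01, each library left out in turn, and the replicate number as a block. Ranges over the alternatives in the report leave out fry, the estimated correlation and the block, the last since nothing in the labels says that equal numbers tie libraries of different lines. The overlap of the tumour lines was set beside that of unchanged groups, simulated with all libraries drawn at MCF10A levels. The tests were tried on simulated data over 17404 genes, where a simulated fold of 8 was called in 98.5%, 95.3% and 99.2% of genes and a fold of 3 in 83.1%, 92.3% and 91.5% (HCC1937 against MCF10A, MDA-MB-231 against MCF10A, MDA-MB-231 against HCC1937). Replicates were checked for copies: chi-square per gene between libraries of a line was 3.39 or more over 15 pairs. The labels name methylation arrays in the wider study, which are not among these files and were not analysed. Genes of the Y chromosome and XIST were left out of all text and plots.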

Results

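The series measured poly(A) RNA in 11 libraries from 3 human mammary cell lines. HCC1937 (n = 4) and MDA-MB-231 (n = 4) are breast carcinoma lines, and MCF10A (n = 3) is a non-tumour mammary epithelial line that serves as the reference. The series title names triple negative breast cancer, so the comparisons ask how the RNA of each tumour line differs from that of the non-tumour line, and how the tumour lines differ from each other. The culture media differed with the line: per the labels' protocols only the MCF10A medium held EGF, cholera toxin, insulin, hydrocortisone and horse serum, while the tumour lines had fetal bovine serum. Nothing in the labels says whether the replicates of a line were separate cultures, so the p-values measure the spread between these libraries and this spread is technical if they were not. Levels are normalised CPM (counts scaled to the library's effective total), given as mean ± SD over the libraries of a line, with the line named first in a comparison printed first.

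Total counts in HCC1937 were 27319691 in replicate 1, 22535099 in replicate 3, 31244933 in replicate 7 and 28357867 in replicate 8. In MDA-MB-231 they were 39227505 in replicate 1, 31934918 in replicate 2, 27257894 in replicate 3 and 30954833 in replicate 4, and in MCF10A 18372374 in replicate 1, 17859926 in replicate 3 and 19478826 in replicate 4. A count of 0 over a whole line allows up to 0.0248 CPM in HCC1937, 0.0238 CPM in MDA-MB-231 and 0.0596 CPM in MCF10A (3 counts over the group). Folds written as at least a value use that floor, and these floors and the counting intervals cover counting error only. All genes of the mitochondrial chromosome, not its mRNAs alone, took 14.8% ± 0.479 (SD) of the counts in MCF10A, 6.36% ± 1.03 in HCC1937 and 3.48% ± 0.252 in MDA-MB-231. For each gene list the adjusted p is that of camera over the 30 lists with a preset correlation, and an estimated value after it is camera's adjusted p with the correlation estimated from the data, given where the preset test called the list. Where leaving out 1 library moved a fold of a named gene by over 1.5 times, the fold without it ends the paragraph. A range after an alternative's adjusted p is that over the list's alternatives. List medians and means are of log2 fold changes. Counts of members adjusted over the list alone equalled those adjusted over all genes in every list and comparison.

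MCF10A replicate 1 stood apart from replicates 3 and 4 in epithelial genes. Of 10802 genes above 5 CPM, 260 were more than 2-fold lower in it than in the mean of the other MCF10A libraries and 55 more than 2-fold higher, while 4 genes differed by that much between replicates 3 and 4. The median difference was -1.16 (log2) over 25 epithelial junction genes and -0.85 over 21 basal genes. CDH1 stood at 169 CPM in replicate 1 against 516 and 514 CPM, and DSG3 at 184 against 684 and 705 CPM.

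Against MCF10A, HCC1937 had low levels of most mesenchymal genes and high levels of KRT8, KRT18 and most interferon-stimulated and antigen presentation genes. FN1, the matrix protein fibronectin, was 357-fold lower (27.5 ± 1.89 against 9826 ± 3831 CPM, log2 fold change -8.48 ± 0.22 SE, adjusted p = 7.14e-15). VIM, the mesenchymal intermediate filament vimentin, was 89.7-fold lower (8.697 ± 0.628 against 781 ± 238 CPM, log2 fold change -6.49 ± 0.16 SE, adjusted p = 6.2e-15), and KRT8, a luminal keratin, was 11.3-fold higher (1714 ± 77.3 against 152 ± 28.6 CPM, log2 fold change 3.50 ± 0.11 SE, adjusted p = 1.28e-13). CDKN2A, which encodes the cell cycle inhibitors p16 and ARF, was 2726-fold higher (95% counting interval 770.3 to 22976, 111 ± 9.85 against 0.0406 ± 0.0351 CPM).

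**Figure D1:**
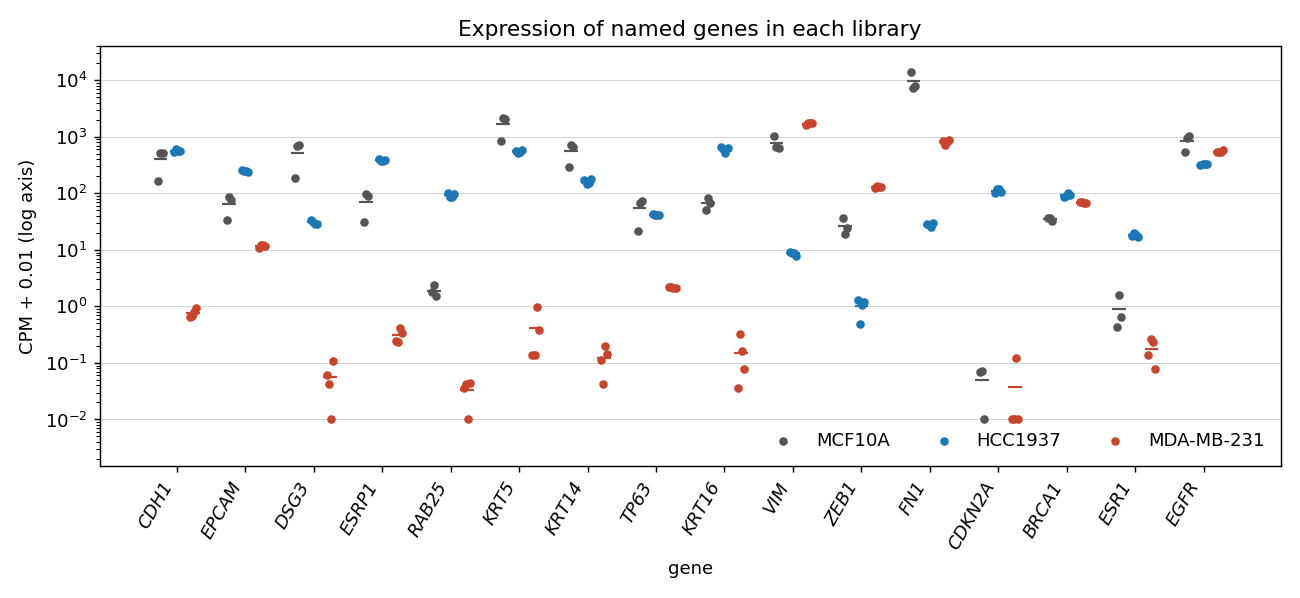
Normalised level (CPM, log axis, with 0.01 CPM added) of 16 genes in each of the 11 libraries, with a point for each library and a horizontal line for the mean of each line. CDH1, EPCAM, KRT5 and KRT14 are lowest in MDA-MB-231, VIM and ZEB1 are lowest in HCC1937 and CDKN2A is near 0 in MCF10A and MDA-MB-231.

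In all, 4114 of 17939 tested genes were higher and 3787 lower in HCC1937. Genes higher made up 52.1% of the calls, and 63.8% when the libraries were scaled by their totals alone, which moved the median of all genes by 0.29 (log2). Among the genes with the largest rise, UCA1 was 1074-fold higher (447 ± 14.9 against 0.416 ± 0.375 CPM), a long non-coding RNA. KLK6 was 411-fold higher (726 ± 83.9 against 1.77 ± 0.369 CPM) and encodes a kallikrein protease. CYBA was 1545-fold higher (125 ± 9.68 against 0.0811 ± 0.0703 CPM) and encodes a subunit of NADPH oxidase. UCA1 was 2179-fold higher without MCF10A replicate 1. CYBA was 1030.2-fold higher without MCF10A replicate 4.

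Among the genes with the largest fall, VCAN, the matrix proteoglycan versican, was at least 23389-fold lower (0 ± 0 against 579.6 ± 94.4 CPM), with 0 counts in HCC1937. GSTP1, a glutathione transferase, was 4034-fold lower (0.202 ± 0.363 against 815 ± 86.8 CPM), and GLUD1, glutamate dehydrogenase, 9563-fold lower (0.06096 ± 0.0759 against 583 ± 90.5 CPM). CADM3 was 39255-fold lower (95% counting interval 8569.8 to 1885900, 0.01005 ± 0.0201 against 394 ± 94.03 CPM). GSTP1 was 38326-fold (95% interval 9713 to 289720) and GLUD1 24262-fold (95% interval 6949 to 207280) lower without HCC1937 replicate 7. CADM3 was at least 12645-fold lower without HCC1937 replicate 3.

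Of the epithelial junction list, 10 of 30 measured members rose, 6 fell and 14 were not called (adjusted p = 0.0229, estimated 0.657). This list lost its call at adjusted p = 0.209 with limma-voom and 0.778 without MCF10A replicate 1 (range 0.00773 to 0.778). GRHL2, an epithelial transcription factor, was 2801-fold higher (95% counting interval 791 to 23603, 114 ± 5.29 against 0.0406 ± 0.0351 CPM). RAB25 was 49.5-fold higher (93.1 ± 6.96 against 1.88 ± 0.435 CPM) and PKP1 47.7-fold higher, while the desmosomal cadherin DSG3 was 17.1-fold lower (30.7 ± 2.15 against 524 ± 295 CPM). Of the key genes, EPCAM was 3.796-fold higher (247 ± 6.08 against 64.97 ± 27.4 CPM), and CDH1 (564 ± 24.6 against 399 ± 199.6 CPM, log2 fold change 0.50, adjusted p = 0.0763) was not called. GRHL2 was 1867-fold (95% interval 517 to 15422) higher without MCF10A replicate 4.

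The basal and myoepithelial list had 13 of 22 members lower and 3 higher without being called as a list (adjusted p = 0.0764), and it was called at adjusted p = 0.0144 with limma-voom, 0.00232 with no filter on low counts and 9.27e-06 without MCF10A replicate 1 (range 9.27e-06 to 0.107). KRT5 and KRT14, basal keratins, fell: KRT5 3.05-fold lower and KRT14 3.44-fold lower. COL17A1 was 11.7-fold lower (57.8 ± 3.48 against 679 ± 347 CPM). In the other direction, OXTR was 148-fold higher (166 ± 6.097 against 1.12 ± 0.324 CPM), the oxytocin receptor, and KRT16 was 8.93-fold higher (605 ± 66.1 against 67.8 ± 16.9 CPM). Not called was TP63 (41.99 ± 1.197 against 54.1 ± 28.2 CPM, log2 fold change -0.36, adjusted p = 0.195), and CD44, a hyaluronan receptor, stood at 1398 ± 48.9 against 1148 ± 233 CPM (log2 fold change 0.28 ± 0.10 SE, adjusted p = 0.0223).

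Of the luminal list, 9 of 20 measured members rose and 3 fell (adjusted p = 0.0144, estimated 0.0854), and it lost its call at adjusted p = 0.1 with limma-voom and 0.0523 without MCF10A replicate 1 (range 0.00664 to 0.1). KRT18 was 5.802-fold higher (1141 ± 116 against 197 ± 17.2 CPM), and ELF5 was at least 236-fold higher (14.1 ± 1.16 against 0 ± 0 CPM). ESR1, the oestrogen receptor, was 20.6-fold higher (18.3 ± 1.39 against 0.886 ± 0.634 CPM). MUC1 was 28.8-fold lower (8.44 ± 0.9296 against 243 ± 95.6 CPM). Below the fold minimum lay GATA3 (30.2 ± 3.11 against 38.7 ± 8.07 CPM, log2 fold change -0.36, adjusted p = 0.0305) and ERBB2 (123 ± 15.02 against 147 ± 11.7 CPM, log2 fold change -0.26, adjusted p = 0.0265), and the sign of ERBB2 turned with library totals alone. PGR, the progesterone receptor, had 0 counts in HCC1937 and MCF10A and was too low to test. ELF5 was at least 154-fold higher without MCF10A replicate 4. ESR1 was 34.8-fold higher without MCF10A replicate 3.

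Mesenchymal genes fell in HCC1937, 19 of 26 with 2 higher (adjusted p = 8.33e-18, estimated 0.0434). ZEB1, a transcription factor of the epithelial-mesenchymal transition, was 26.8-fold lower (1.00 ± 0.363 against 26.8 ± 8.85 CPM). CDH2 was 154-fold lower (0.546 ± 0.125 against 84.3 ± 18.8 CPM) and LOX 83.1-fold lower. Fibroblast markers fell in 9 of 12 (adjusted p = 3.1e-11, estimated 0.00979): decorin, DCN, was 4791-fold lower (0.0786 ± 0.0877 against 376 ± 86.7 CPM), POSTN 2236-fold lower and FAP 624-fold lower. Pericellular protease genes fell in 15 of 23 (adjusted p = 5.05e-09, estimated 0.0274), and PLAT was 63.1-fold lower (4.04 ± 1.04 against 255 ± 48.5 CPM). Of 23 collagen genes, 12 fell and 5 rose (adjusted p = 0.0471, estimated 0.225). COL8A1 was 230.7-fold lower (9.60 ± 1.801 against 2215 ± 849 CPM), while COL5A1 was 474-fold higher (56.4 ± 4.04 against 0.119 ± 0.159 CPM). The collagen list lost its call at adjusted p = 0.0569 with library totals alone, 0.0652 with a filter of 1 CPM in 3 libraries, 0.052 with only the compared lines fitted, 0.0924, 0.072, 0.0704 and 0.0759 without HCC1937 replicates 1, 3, 7 and 8 and 0.0508, 0.0549 and 0.0548 without MDA-MB-231 replicates 1, 2 and 4 (range 0.00126 to 0.0924). DCN was 9918-fold (95% interval 3697 to 52393) lower without HCC1937 replicate 7. COL5A1 was 1968-fold (95% interval 340.4 to 74923) higher without MCF10A replicate 1.

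Interferon-stimulated genes rose in 24 of 29 measured members and fell in 3 (adjusted p = 2.15e-11, estimated 0.0434). The antiviral genes MX1 116-fold higher and OASL 76.8-fold higher were among them. Antigen presentation genes rose in 15 of 23 (adjusted p = 1.61e-06, estimated 0.0434), with CD74 250.2-fold higher, the class II invariant chain, and PSMB9 13.6-fold higher, an immunoproteasome subunit. Among cytokines and chemokines, 7 of 24 rose and 9 fell (adjusted p = 0.567, median 0.06, mean -0.68, test pointing down). The median turned to -0.35 without MCF10A replicate 1 and to -0.25 and -0.25 without MDA-MB-231 replicates 2 and 3, and the balance to 9 higher and 8 lower with library totals alone. CXCL8 was 60.2-fold lower (5.896 ± 6.25 against 355 ± 39.1 CPM) and CXCL1 41.6-fold lower, while CCL5 was 134-fold higher (13.1 ± 0.856 against 0.0973 ± 0.0882 CPM). MX1 was 189.9-fold and CD74 422-fold higher without MCF10A replicate 1. CXCL8 was 126-fold and CXCL1 74.1-fold lower without HCC1937 replicate 3. CCL5 was 218-fold (95% interval 59.4 to 1772) higher without MCF10A replicate 4.

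Cell cycle genes rose in 14 of 30 members (adjusted p = 4.46e-08, estimated 0.0648), with MYBL2 6.73-fold higher and E2F1 6.85-fold higher. MKI67 (375 ± 73.3 against 203 ± 23.1 CPM, log2 fold change 0.89, adjusted p = 1.49e-05) lay under the fold minimum, which it passed at 1.18 with library totals alone and 1.03 without MCF10A replicate 1 (log2). MYC was 2.81-fold lower (117 ± 13.03 against 327 ± 86.6 CPM). Homologous recombination genes rose in 9 of 30 and fell in 2 (adjusted p = 0.00956, estimated 0.0533): RAD51AP1 5.39-fold higher, BRCA1 2.65-fold higher and BRCA2 2.31-fold higher. The labels of HCC1937 disagree on whether its BRCA1 is wild type or mutant. ATM was 3.36-fold lower (44.7 ± 4.87 against 150.4 ± 3.36 CPM), FANCC 3.47-fold higher and RBBP8 3.32-fold higher. Direct targets of p53 fell in 17 of 30 (adjusted p = 5.89e-06, estimated 0.0434), CDKN1A 2.45-fold lower and TNFRSF10B 8.16-fold lower among them. SPATA18 was at least 883-fold lower (0 ± 0 against 21.9 ± 2.05 CPM) and PTCHD4 226-fold lower. PTCHD4 was 486-fold (95% interval 153 to 2164) lower without HCC1937 replicate 3.

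Of the 7 genes at loci often reported as deleted in 1 of these lines, 5 rose and 1 fell (adjusted p = 0.0172, estimated 0.225), and this list lost its call at adjusted p = 0.299 with limma-voom, 0.0577 with no filter on low counts and 0.0523 without MCF10A replicate 1 (range 0.00622 to 0.299). The low side of the rises was MCF10A, where CDKN2A (ENSG00000147889, chromosome 9, 21967753 to 21995301, GRCh38) and its neighbour were near 0: MTAP was 2168-fold higher (95% counting interval 603 to 17983, 86.6 ± 5.49 against 0.0399 ± 0.0691 CPM). Of 20 DNA methylation genes, 3 rose and 2 fell (adjusted p = 0.623): DNMT3B 5.098-fold higher, IDH2 6.68-fold higher and TET1 2.34-fold higher. MBD1 was 3.73-fold lower (23.7 ± 1.31 against 88.5 ± 5.17 CPM) and MBD2 3.003-fold lower. Under the fold minimum lay DNMT1 (241 ± 23.9 against 122 ± 9.77 CPM, log2 fold change 0.98, adjusted p = 9.53e-08), DNMT3A (18.02 ± 1.59 against 10.8 ± 1.03 CPM, log2 fold change 0.74, adjusted p = 6.07e-05) and TET2 (39.5 ± 2.39 against 39.8 ± 2.52 CPM, log2 fold change -0.01, adjusted p = 0.92). The sign of TET2 turned with other scalings and filters. DNMT1 passed that minimum at 1.03 with DESeq2, 1.02 with RLE size factors, 1.06 with upper-quartile scaling, 1.27 with library totals alone, 1.07 with no filter on low counts, 1.01 with only the compared lines fitted, 1.05 and 1.02 without HCC1937 replicates 1 and 3 and 1.10 and 1.00 without MCF10A replicates 1 and 4, and DNMT3A at 1.03 with library totals alone. Histone modifiers had 1 of 40 higher and 3 lower (adjusted p = 0.897), a balance that turned with library totals alone, with SUZ12 2.39-fold higher, SETDB1 4.24-fold lower and KDM5B 3.06-fold lower. EZH2 (53.1 ± 3.85 against 37.3 ± 1.13 CPM, log2 fold change 0.51, adjusted p = 1.23e-05) was not called. Replication-dependent histone mRNAs, which mostly lack a poly(A) tail, rose in 14 of 17 (adjusted p = 0.00771, estimated 0.225, median 1.83 or, with near-0 members at their bound, 1.81), with H4C8 6.25-fold higher. MTAP was at least 970.02-fold higher without MCF10A replicate 1.

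Glucocorticoid-responsive genes fell in 17 of 24 and rose in 2 (adjusted p = 9.86e-11, estimated 0.0274), hydrocortisone being in the MCF10A medium alone. ZBTB16, a transcription factor, was at least 5971-fold lower (0 ± 0 against 148 ± 31.6 CPM) and DUSP1 16.9-fold lower. Genes of the cAMP response fell in 11 of 20 and rose in 5 (adjusted p = 0.000185, estimated 0.0533), cholera toxin being in the same medium, with PDE4D 756-fold lower. EGFR ligands and targets fell in 8 of 26 and rose in 3 (adjusted p = 0.12), where the medium held EGF: AREG 13.5-fold lower, DUSP6 6.59-fold lower and EPGN 11.2-fold lower. SPRY1 was 9.52-fold lower (2.03 ± 0.302 against 19.3 ± 2.53 CPM), and EGFR was 2.57-fold lower (328 ± 4.902 against 841 ± 266 CPM). This list was called at adjusted p = 0.0335 without MCF10A replicate 1 (range 0.0335 to 0.296), and its median near 0 turned positive under several, with 0.29 with library totals alone and 0.01, 0.02 and 0.07 without MCF10A replicates 1, 3 and 4. PDE4D was 1627-fold (95% interval 571 to 8087) lower without HCC1937 replicate 7.

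All 13 mitochondrially encoded mRNAs were lower in HCC1937 (adjusted p = 6.82e-08, estimated 0.192), with MT-CO1 4.696-fold lower and MT-ND3 6.72-fold lower. Ribosomal protein genes fell in 8 of 53 and rose in 1 (adjusted p = 0.0214, estimated 0.659), with RPL22L1 4.22-fold lower, and the list lost its call at adjusted p = 0.118 with library totals alone, 0.0574 without HCC1937 replicate 3 and 0.075 without MCF10A replicate 1 (range 0.000187 to 0.118). Cholesterol genes fell in 12 of 26 and rose in 2 (adjusted p = 0.000879, estimated 0.262): FDPS 4.82-fold lower and EBP 3.53-fold lower. Fatty acid genes had 3 of 22 higher and 6 lower (adjusted p = 0.254, median -0.67, mean 0.15, test pointing down). PLIN2, which coats lipid droplets, was 583-fold higher (93.4 ± 6.64 against 0.1603 ± 0.226 CPM), and GPAM was 6.11-fold lower (17.6 ± 0.954 against 107 ± 29.6 CPM). The fatty acid list was called at adjusted p = 0.0421 with limma-voom, 0.0466 with no filter on low counts and 0.0486 without MCF10A replicate 1 (range 0.0421 to 0.376). Glycolysis and hypoxia genes had 5 of 30 higher and 5 lower (adjusted p = 0.518, median 0.05, mean -0.25, test pointing down), with CA12 14.9-fold lower and SLC16A3 8.29-fold lower. NRF2 targets had 7 of 24 higher and 7 lower (adjusted p = 0.285), their median turning to 0.14 with library totals alone and 0.05 without MCF10A replicate 1, with AKR1C2 7.95-fold lower and GSTM3 618-fold higher (95% counting interval 209.6 to 2969.5). PLIN2 was 3023-fold (95% interval 564 to 124060) and GSTM3 1274-fold (95% interval 220.3 to 48482) higher without MCF10A replicate 1.

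Epidermal differentiation genes had 13 of 30 higher and 8 lower (adjusted p = 0.183), with LCN2 81.7-fold higher and KLK5 28.6-fold higher. Stress response genes had 7 of 24 higher and 3 lower (adjusted p = 0.077), with the serine synthesis enzymes PHGDH 9.14-fold higher and PSAT1 12.04-fold higher, and the list was called at adjusted p = 0.0494 with library totals alone (range 0.0494 to 0.299). Of 7 measured cancer/testis genes, 1 rose and 6 were not called (adjusted p = 0.894, median 0.00). The gene that rose, ACTL8, had the list's highest log2 fold change, 2.88. Of 8 measured leukocyte and endothelial markers, 5 rose and 2 fell (adjusted p = 0.421), PECAM1 6.097-fold higher among them.

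Each gene named above as changed between HCC1937 and MCF10A had an edgeR adjusted p between 1.88e-16 and 0.000311, and the CPM of its 4 HCC1937 and 3 MCF10A libraries did not overlap. Medium and line cannot be separated, and keratins, HLA, kallikrein, AKR1C and histone genes have near-identical relatives with which they share reads.

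Against MCF10A, MDA-MB-231 had low levels of most epithelial, basal and epidermal differentiation genes and higher levels of cell cycle and most interferon-stimulated genes. CDH1, which encodes E-cadherin (ENSG00000039068, chromosome 16, 68737292 to 68835541), was 528-fold lower (0.756 ± 0.136 against 399 ± 199.6 CPM, log2 fold change -9.05 ± 0.37 SE, adjusted p = 1.51e-12). KRT5, a basal keratin, was 4238-fold lower (0.401 ± 0.401 against 1699 ± 754 CPM, log2 fold change -12.15 ± 0.43 SE, adjusted p = 2.93e-13). VIM was 2.21-fold higher (1722 ± 55.1 against 781 ± 238 CPM, log2 fold change 1.14 ± 0.14 SE, adjusted p = 1.2e-06), and MKI67, a marker of cycling cells, 3.67-fold higher (744 ± 74.7 against 203 ± 23.1 CPM, log2 fold change 1.88 ± 0.14 SE, adjusted p = 2.85e-09). KRT5 was 8150.3-fold lower without MDA-MB-231 replicate 3.

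Among 17939 tested genes, 3359 were higher in MDA-MB-231 and 4255 lower. Library totals alone moved the median of all genes by 0.11 and upper-quartile scaling by -0.13 (log2), and 44.1% of the calls were higher, against 48.8% and 38.97% with those scalings. The strongest rises included FLNC 506-fold higher, a filamin, and KRT19 699-fold higher, a keratin. ADGRF5 was 926-fold higher (239.97 ± 5.59 against 0.259 ± 0.242 CPM), and BCAT1 was 629-fold higher (226 ± 29.1 against 0.359 ± 0.415 CPM), a branched-chain aminotransferase. The cystatins CST1 859-fold higher and CST4 1598-fold higher rose. EDIL3 was 631-fold higher (214 ± 12.7 against 0.339 ± 0.588 CPM), NIBAN1 508-fold higher and ESAM 269-fold higher. FLNC was 988-fold, KRT19 1176-fold, ADGRF5 2014-fold, BCAT1 1896-fold, CST1 6673-fold (95% interval 1244 to 273870), CST4 at least 1430.1-fold, EDIL3 at least 2398-fold, NIBAN1 1150.4-fold and ESAM 529-fold higher without MCF10A replicate 1.

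The strongest falls included the keratins KRT6A 6182-fold lower, KRT17 4008-fold lower and KRT14 4937-fold lower. ANPEP was 2864-fold lower (0.501 ± 0.645 against 1434 ± 97.97 CPM), an aminopeptidase, and IL1RL1 was 3160.3-fold lower (0.276 ± 0.324 against 873 ± 84.8 CPM), the IL-33 receptor. C3 was 653-fold lower (3.57 ± 0.892 against 2329.5 ± 164 CPM), a complement component, SERPINB5 1931-fold lower, maspin, and CD109 873-fold lower. KRT17 was 9395-fold, ANPEP 8024-fold and IL1RL1 7427-fold lower without MDA-MB-231 replicate 3.

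Epithelial junction genes fell in 24 of 30 members and rose in 1 (adjusted p = 6.85e-11, estimated 0.258). The desmosomal cadherins DSG3 11378-fold lower and DSC3 2497-fold lower fell with CDH3 1157-fold lower and EPCAM 5.504-fold lower. Basal genes fell in 16 of 22 and rose in 2 (adjusted p = 7.06e-11, estimated 0.0771), with TP63, a transcription factor of basal cells, 25.4-fold lower (2.13 ± 0.0546 against 54.1 ± 28.2 CPM). MCF10A replicate 1 was itself lower in both lists, as given above. CD44 (639.99 ± 17.1 against 1148 ± 233 CPM, log2 fold change -0.84, adjusted p = 1.6e-06) was not called. Luminal genes had 8 of 20 higher and 9 lower (adjusted p = 0.966, median -0.28 or, with near-0 members at their bound, -0.57, mean 0.99, test pointing up), a balance that turned with no filter on low counts. SPDEF was 1183-fold higher (95% counting interval 322 to 9604, 46.2 ± 4.17 against 0.0391 ± 0.0339 CPM), AGR2 57.9-fold higher and CD24 21.2-fold lower. ESR1 was 5.21-fold lower (0.1698 ± 0.08697 against 0.886 ± 0.634 CPM) and GATA3 4.78-fold lower. ERBB2 was 2.05-fold lower (71.96 ± 7.48 against 147 ± 11.7 CPM), near the fold minimum, which it missed at -0.93 with library totals alone, -0.96 with no filter on low counts, -0.99 and -0.99 without MDA-MB-231 replicates 2 and 3 and -0.96 and -0.99 without MCF10A replicates 3 and 4 (log2). KRT18 (341 ± 24.8 against 197 ± 17.2 CPM, log2 fold change 0.80, adjusted p = 8.21e-07) was not called, and PGR stood at 0.0678 ± 0.0465 against 0 ± 0 CPM, too low to test. DSG3 was 18631-fold (95% interval 5740.3 to 81347) lower without MDA-MB-231 replicate 4. DSC3 was 4938-fold lower without MDA-MB-231 replicate 3. Without MCF10A replicate 3 SPDEF was 789-fold (95% interval 218 to 6516) higher and ESR1 3.09-fold lower.

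Of 26 mesenchymal genes, 8 rose and 11 fell (adjusted p = 0.00282, estimated 0.38), and the list lost its call at adjusted p = 0.112 with limma-voom (range 0.000368 to 0.112). ZEB1 was 4.84-fold higher (129.6 ± 3.204 against 26.8 ± 8.85 CPM) and CDH11 168-fold higher, while TGFBI was 62.8-fold lower (35.7 ± 1.98 against 2240.4 ± 57.3 CPM), SPARC 126-fold lower and CDH2 96.0-fold lower. Fibroblast markers fell in 6 of 12 and rose in 3 (adjusted p = 6.46e-08, estimated 0.0144), among them DCN 1497-fold lower, POSTN 4288-fold lower and FBLN1 176-fold lower, and this list lost its call at adjusted p = 0.217 with limma-voom (range 4.38e-10 to 0.217). Pericellular protease genes fell in 12 of 23 and rose in 3 (adjusted p = 0.00282, estimated 0.122): MMP2 774-fold lower, MMP28 277-fold lower and MMP1 32.4-fold higher. The protease list lost its call at adjusted p = 0.0524 with limma-voom (range 0.000154 to 0.0524). Collagens had 6 of 23 higher and 11 lower (adjusted p = 0.43), COL13A1 178-fold higher and COL4A6 133-fold lower at the ends. DCN was 2356-fold and POSTN 19364-fold (95% interval 4658 to 138940) lower without MDA-MB-231 replicate 3.

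Interferon-stimulated genes rose in 18 of 29 and fell in 4 (adjusted p = 6.1e-06, estimated 0.12). IFIT1 was 35.9-fold higher (114 ± 6.63 against 3.17 ± 1.799 CPM), IFIT2 27.4-fold higher and OAS2 28.04-fold higher, while IFI44L was 22.1-fold lower (2.499 ± 0.0634 against 55.3 ± 25.5 CPM). Antigen presentation genes rose in 11 of 23 and fell in 1 (adjusted p = 0.000365, estimated 0.107), with CD74 236-fold higher and HLA-DRA 137-fold higher. Cytokine and chemokine genes fell in 14 of 24 and rose in 6 (adjusted p = 0.0412, estimated 0.553): CXCL1 134-fold lower, CXCL8 40.4-fold lower and IL1A 146-fold lower. This list lost its call at adjusted p = 0.0524 with limma-voom, 0.062 with upper-quartile scaling, 0.0509 without HCC1937 replicate 1 and 0.0519 without MDA-MB-231 replicate 4 (range 0.00213 to 0.062). CD74 was 399-fold higher without MCF10A replicate 1. HLA-DRA was 206-fold (95% interval 70.2 to 995) higher without MCF10A replicate 4.

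Cell cycle genes rose in 22 of 30 (adjusted p = 3.59e-12, estimated 0.0314), with FOXM1 5.23-fold higher, E2F1 4.97-fold higher and AURKA 4.04-fold higher, while MYC was 3.46-fold lower (94.4 ± 5.71 against 327 ± 86.6 CPM). Homologous recombination genes rose in 11 of 30 and fell in 1 (adjusted p = 0.0032, estimated 0.0426): RAD51AP1 6.41-fold higher, FANCB 3.49-fold higher and RAD50 2.98-fold lower. BRCA2 was 2.03-fold higher (57.2 ± 2.98 against 28.2 ± 5.88 CPM), a call missed at 0.89 with upper-quartile scaling, 0.97 with a filter of 1 CPM in 3 libraries, 0.96 with only the compared lines fitted, 0.99 without MDA-MB-231 replicate 2 and 0.89 without MCF10A replicate 1 (log2). BRCA1 (68.3 ± 1.41 against 35.1 ± 2.14 CPM, log2 fold change 0.96, adjusted p = 1.31e-08) lay just under the fold minimum, which it passed at 1.07 with library totals alone, 1.03 with no filter on low counts and 1.02 and 1.01 without MCF10A replicates 1 and 3. Targets of p53 fell in 22 of 30 (adjusted p = 8.36e-09, estimated 0.0251), with CDKN1A 3.16-fold lower, BTG2 61.4-fold lower and FAS 14.9-fold lower.

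Of the 7 genes at often deleted loci, 2 fell and 5 were not called (adjusted p = 0.893, median -0.64 or, with near-0 members at their bound, -1.73), the median being 0.60 with only the compared lines fitted and 0.61 without MCF10A replicate 1. ELAVL2 was 613-fold lower (95% counting interval 111 to 24402, 0.007998 ± 0.01599 against 4.903 ± 2.08 CPM), and DMRTA1 was at least 17.4-fold lower (0 ± 0 against 0.414 ± 0.199 CPM). CDKN2A (0.0282 ± 0.0564 against 0.0406 ± 0.0351 CPM) and MTAP (0.009405 ± 0.0188 against 0.0399 ± 0.0691 CPM) were near 0 counts in both lines, so no difference was detectable. DNA methylation genes had 5 of 20 higher and 4 lower (adjusted p = 0.968, median -0.05, mean 0.13, test pointing down), and the median turned positive with several alternatives, up to 0.06 with library totals alone. DNMT1 was 3.14-fold higher (383 ± 33.1 against 122 ± 9.77 CPM), DNMT3B 2.74-fold higher and TET1 3.26-fold higher, while DNMT3A (7.59 ± 0.873 against 10.8 ± 1.03 CPM, log2 fold change -0.51, adjusted p = 0.0019) and TET2 (36.5 ± 1.72 against 39.8 ± 2.52 CPM, log2 fold change -0.12, adjusted p = 0.179) were not called. Histone modifiers rose in 12 of 40 and fell in 2 (adjusted p = 0.0412, estimated 0.38), EZH2, the catalytic subunit of PRC2, being 3.42-fold higher (128 ± 4.52 against 37.3 ± 1.13 CPM) and KDM5B 3.14-fold lower. The list lost its call at adjusted p = 0.0524 with limma-voom, 0.0739 with upper-quartile scaling, 0.0869 with a filter of 1 CPM in 3 libraries and 0.0714 with only the compared lines fitted (range 0.00135 to 0.0869). Replication-dependent histones had 4 of 17 higher and 6 lower (adjusted p = 0.895, median 0.42, mean -0.86, test pointing up), turning to 4 higher and 2 lower of 13 with only the compared lines fitted, with H2BC8 at least 34.1-fold lower. ELAVL2 was at least 155-fold lower without MDA-MB-231 replicate 2.

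Epidermal differentiation genes fell in 27 of 30 and rose in 1 (adjusted p = 4.27e-23, estimated 0.0144, median -8.32 or, with near-0 members at their bound, -7.82), with the protease inhibitors SLPI 823-fold lower and PI3 1432-fold lower and the kallikrein KLK10 2064-fold lower. Glucocorticoid-responsive genes fell in 14 of 24 and rose in 3 (adjusted p = 1.08e-08, estimated 0.0251), against MCF10A cells grown with hydrocortisone: ZBTB16 2020-fold lower, TFCP2L1 61.6-fold lower and SGK1 9.56-fold lower. Genes of the cAMP response had 6 of 20 higher and 7 lower (adjusted p = 0.895, median -0.49, mean 0.24, test pointing down), cholera toxin being in the MCF10A medium, with GEM 192-fold higher and PER1 5.93-fold lower. EGFR ligands and targets rose in 16 of 26 and fell in 4 (adjusted p = 0.000736, estimated 0.228) with EGF in the MCF10A medium alone: FOSL1 8.84-fold higher, NRG1 7.21-fold higher and EPGN 1109-fold lower. EGFR (549 ± 22.1 against 841 ± 266 CPM, log2 fold change -0.62, adjusted p = 0.00126) was not called. PI3 was 3179-fold lower without MDA-MB-231 replicate 3. GEM was 331-fold higher without MCF10A replicate 3.

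All 13 mitochondrially encoded mRNAs fell (adjusted p = 2.97e-09, estimated 0.168), MT-CYB being 6.78-fold lower (1876 ± 137 against 12724 ± 466 CPM). Ribosomal protein genes fell in 6 of 53 and rose in 1 (adjusted p = 0.00463, estimated 0.648), with RPLP1 2.801-fold lower. Glycolysis and hypoxia genes rose in 14 of 30 and fell in 2 (adjusted p = 0.00102, estimated 0.0554), ENO2, an enolase, being 16.6-fold higher (166 ± 7.51 against 10.01 ± 4.27 CPM) and SLC2A3, a glucose transporter, 13.1-fold higher (59.9 ± 2.38 against 4.56 ± 0.778 CPM). NRF2 targets fell in 8 of 24 and rose in 3 (adjusted p = 0.013, estimated 0.526), with AKR1C2 792-fold lower and ABCC3 13.2-fold lower, and the list lost its call at adjusted p = 0.142 with limma-voom and 0.0964 with no filter on low counts (range 0.00372 to 0.142). Cholesterol genes had 2 of 26 higher and 7 lower (adjusted p = 0.222), with SQLE 9.02-fold lower, and this list was called at adjusted p = 0.0351 without MCF10A replicate 1 (range 0.0351 to 0.322). Fatty acid genes had 7 of 22 higher and 3 lower (adjusted p = 0.463), with FADS2 4.03-fold higher. Stress response genes had 5 of 24 higher and 8 lower (adjusted p = 0.196), STC2 being 243-fold lower (1.04 ± 0.273 against 253 ± 80.1 CPM), and the list was called at adjusted p = 0.048 without MCF10A replicate 1 (range 0.048 to 0.273). Of 7 measured cancer/testis genes 6 rose and 1 fell (adjusted p = 0.103, median 7.44 or, with near-0 members at their bound, 3.89), with MAGEC2 at least 36.7-fold higher and MAEL at least 34.8-fold higher, and the list was called at adjusted p = 0.0197 with limma-voom and 0.0409 with only the compared lines fitted (range 0.0197 to 0.285). Leukocyte and endothelial markers had 2 of 8 higher and 2 lower (adjusted p = 0.968, median -0.00, mean -0.09, test pointing up), the median turning positive with several alternatives, up to 1.40 with no filter on low counts and, of left-out libraries, 0.82 without MCF10A replicate 3, with CD14 28.8-fold lower and PECAM1 7.11-fold higher. MAGEC2 was at least 24.01-fold and MAEL at least 22.8-fold higher without MCF10A replicate 4.

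The edgeR adjusted p of the genes named above as changed between MDA-MB-231 and MCF10A lay between 4.79e-18 and 0.000264, and their CPM did not overlap between the 4 MDA-MB-231 and the 3 MCF10A libraries. Medium and line are again confounded, and the cystatins, SSX, MAGE and keratin families carry the same doubt about shared reads.

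Between the tumour lines, HCC1937 expressed most epithelial and basal genes at higher levels and MDA-MB-231 most of the mesenchymal genes. VIM was 198-fold higher (1722 ± 55.1 against 8.697 ± 0.628 CPM, log2 fold change 7.63 ± 0.17 SE, adjusted p = 8.06e-16) in MDA-MB-231 than in HCC1937, and ZEB1 129.7-fold higher (129.6 ± 3.204 against 1.00 ± 0.363 CPM, log2 fold change 6.98 ± 0.21 SE, adjusted p = 3.02e-14). CDH1 was 746-fold lower (0.756 ± 0.136 against 564 ± 24.6 CPM, log2 fold change -9.55 ± 0.36 SE, adjusted p = 4.69e-13), and LCN2, the secreted protein lipocalin 2, 2799-fold lower (0.371 ± 0.0889 against 1039 ± 30.2 CPM, log2 fold change -11.45 ± 0.13 SE, adjusted p = 1.47e-18). CDKN2A was 3919.6-fold lower (95% counting interval 1589 to 22524, 0.0282 ± 0.0564 against 111 ± 9.85 CPM). CDKN2A was at least 3665-fold lower without MDA-MB-231 replicate 3.

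Of 17939 tested genes, 3652 were higher and 4670 lower in MDA-MB-231. Library totals alone moved the median of all genes by -0.18 and upper-quartile scaling by -0.20 (log2), which took the share of calls that were higher from 43.9% to 36.8% and 36.2%. The largest rises included CST3 3691-fold higher, cystatin C, EDIL3 4019-fold higher and ENPP1 1061-fold higher. GLUD1 was 4413-fold higher (269 ± 8.53 against 0.06096 ± 0.0759 CPM) and ADGRF5 274-fold higher. The largest falls included KLK5 7711-fold lower, KLK6 7024-fold lower and RARRES1 6832-fold lower. PI3 was 3544-fold lower (0.199 ± 0.219 against 705 ± 42.6 CPM), and SLC16A1 was 977-fold lower (0.603 ± 0.381 against 589 ± 18.6 CPM), a lactate transporter. EDIL3 was 6947-fold (95% interval 2347 to 33265) higher without HCC1937 replicate 3. GLUD1 was 11196-fold (95% interval 3207 to 95648) higher without HCC1937 replicate 7. PI3 was 7866-fold lower without MDA-MB-231 replicate 3.

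Epithelial junction genes fell in 28 of 30 (adjusted p = 3.33e-15, estimated 0.255), with ESRP1, a splicing factor of epithelial cells, 1279-fold lower (0.302 ± 0.0893 against 386 ± 17.2 CPM), CDH3 997-fold lower and EPCAM 20.9-fold lower. Basal genes fell in 14 of 22 and rose in 3 (adjusted p = 1.84e-05, estimated 0.255): KRT5 1388-fold lower, KRT14 1436-fold lower and KRT15 313-fold lower. TP63 was 19.7-fold lower (2.13 ± 0.0546 against 41.99 ± 1.197 CPM), and CD44 was 2.18-fold lower (639.99 ± 17.1 against 1398 ± 48.9 CPM). Mesenchymal genes rose in 15 of 26 and fell in 6 (adjusted p = 5.51e-06, estimated 0.268, median 1.94 or, with near-0 members at their bound, 2.15), with LOX 66.01-fold higher and GNG11 138-fold higher. Luminal genes had 8 of 20 higher and 10 lower (adjusted p = 0.142): KRT19 35.6-fold higher, KRT18 3.34-fold lower and ELF3 25.1-fold lower. ESR1 was 108-fold lower (0.1698 ± 0.08697 against 18.3 ± 1.39 CPM) and GATA3 3.74-fold lower. ERBB2 (71.96 ± 7.48 against 123 ± 15.02 CPM, log2 fold change -0.77, adjusted p = 1.2e-06) was not called, and PGR was at 0.0678 ± 0.0465 against 0 ± 0 CPM. Epidermal differentiation genes fell in 27 of 30 and rose in 1 (adjusted p = 1.49e-22, estimated 0.0373, median -9.13 or, with near-0 members at their bound, -8.53). KRT5 was 2669.6-fold lower without MDA-MB-231 replicate 3.

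Pericellular protease genes rose in 13 of 23 and fell in 6 (adjusted p = 0.0182, estimated 0.274), with MMP14, a membrane-bound metalloproteinase, 30.5-fold higher (697 ± 30.7 against 22.8 ± 2.91 CPM), PLAT 62.04-fold higher and MMP28 131-fold lower. Collagens had 7 of 23 higher and 4 lower (adjusted p = 0.327), with COL6A3 113-fold higher. Fibroblast markers had 5 of 12 higher and 2 lower (adjusted p = 0.428), with MCAM 16.98-fold higher and FBLN1 24.9-fold lower. EGFR ligands and targets rose in 16 of 26 and fell in 2 (adjusted p = 1.84e-05, estimated 0.253), the MAPK phosphatases DUSP6 31.3-fold higher and DUSP4 24.9-fold higher and the inhibitor SPRY1 34.8-fold higher among them. EGFR (549 ± 22.1 against 328 ± 4.902 CPM, log2 fold change 0.74, adjusted p = 0.000115) was not called. Genes of the cAMP response rose in 9 of 20 and fell in 3 (adjusted p = 0.00189, estimated 0.253, median 1.01 or, with near-0 members at their bound, 0.84), with PDE4D 874-fold higher and GEM 328-fold higher, and this list lost its call at adjusted p = 0.0835 with limma-voom (range 0.000862 to 0.0835). Glucocorticoid-responsive genes had 11 of 24 higher and 5 lower (adjusted p = 0.463), with MT1E 7.69-fold higher. The media of these lines differ in base medium and neither names hydrocortisone, cholera toxin or EGF. PDE4D was 1882-fold (95% interval 660.0 to 9353) higher without HCC1937 replicate 7.

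Interferon-stimulated genes fell in 15 of 29 and rose in 7 (adjusted p = 0.0268, estimated 0.421), MX2 38.4-fold lower, OAS1 14.96-fold lower and IRF7 71.3-fold higher, and the list lost its call at adjusted p = 0.0616 with only the compared lines fitted (range 0.0038 to 0.0616). Antigen presentation genes had 7 of 23 higher and 6 lower (adjusted p = 0.399), a balance that turned with upper-quartile and library-total scaling, with HLA-B 3.37-fold lower. Cytokines and chemokines had 5 of 24 higher and 9 lower (adjusted p = 0.274), with CXCL16 121-fold lower and IL11 32.8-fold higher. Cell cycle genes had 7 of 30 higher and 3 lower (adjusted p = 0.225), with CDK1 3.00-fold higher and MYBL2 3.27-fold lower, and the list was called at adjusted p = 0.0276 with no filter on low counts (range 0.0276 to 0.356). MKI67 (744 ± 74.7 against 375 ± 73.3 CPM, log2 fold change 0.99, adjusted p = 1.2e-06) lay at the fold minimum, which it passed at 1.00 with limma-voom, 1.07 and 1.05 without HCC1937 replicates 7 and 8 and 1.02 and 1.04 without MDA-MB-231 replicates 2 and 3 (log2). MYC (94.4 ± 5.71 against 117 ± 13.03 CPM, log2 fold change -0.30, adjusted p = 0.042) was not called. Homologous recombination genes had 4 of 30 higher and 2 lower (adjusted p = 0.78, median -0.13, mean 0.05, test pointing up), with FANCI 3.04-fold higher and ATM 2.33-fold higher. BRCA1 (68.3 ± 1.41 against 93.3 ± 7.56 CPM, log2 fold change -0.45, adjusted p = 1.74e-05) and BRCA2 (57.2 ± 2.98 against 65.1 ± 6.21 CPM, log2 fold change -0.19, adjusted p = 0.107) were not called. Targets of p53 had 4 of 30 higher and 7 lower (adjusted p = 0.374), with PHLDA3 9.104-fold lower. CDKN1A (68.3 ± 2.44 against 88.1 ± 5.62 CPM, log2 fold change -0.37, adjusted p = 6.14e-05) was not called.

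At the often deleted loci 2 of 7 genes rose and 5 fell (adjusted p = 0.00283, estimated 0.253), with MTAP 9203-fold lower (95% counting interval 1958 to 430780), and the list lost its call at adjusted p = 0.2 with limma-voom (range 0.00137 to 0.2). DNA methylation genes had 2 of 20 higher and 4 lower (adjusted p = 0.634, median 0.17, mean -0.11, test pointing down), and the median turned negative with upper-quartile and library-total scaling. DNMT3A was 2.37-fold lower (7.59 ± 0.873 against 18.02 ± 1.59 CPM), TET3 2.85-fold lower and UHRF1 2.42-fold higher. Under the fold minimum lay DNMT1 (383 ± 33.1 against 241 ± 23.9 CPM, log2 fold change 0.67, adjusted p = 1.99e-06), TET1 (3.79 ± 0.704 against 2.72 ± 0.177 CPM, log2 fold change 0.47, adjusted p = 0.0298) and TET2 (36.5 ± 1.72 against 39.5 ± 2.39 CPM, log2 fold change -0.11, adjusted p = 0.166), as well as DNMT3B (10.8 ± 1.35 against 20.04 ± 1.34 CPM, log2 fold change -0.89, adjusted p = 1.17e-06), which passed it at -1.10 with upper-quartile scaling and -1.07 with library totals alone. Histone modifiers had 6 of 40 higher (adjusted p = 0.09), with NSD2 3.92-fold higher and EZH2 2.403-fold higher, and the list was called at adjusted p = 0.0408 with limma-voom and 0.00328 with no filter on low counts (range 0.00328 to 0.176). Replication-dependent histones fell in 11 of 17 and rose in 3 (adjusted p = 0.0386, estimated 0.469), with H2AC6 4.71-fold lower and H3C8 at least 125-fold lower. The histone list lost its call at adjusted p = 0.0557 with upper-quartile scaling, 0.0559 with library totals alone, 0.0584 with a filter of 1 CPM in 3 libraries, 0.0682 with only the compared lines fitted and 0.147, 0.0774 and 0.0791 without MCF10A replicates 1, 3 and 4 (range 0.0156 to 0.147). MTAP was at least 2868-fold lower without MDA-MB-231 replicate 3.

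Glycolysis and hypoxia genes rose in 12 of 30 and fell in 1 (adjusted p = 0.000378, estimated 0.0899), SLC2A3 338-fold higher and PFKP 4.88-fold higher, a phosphofructokinase. Stress response genes fell in 10 of 24 and rose in 4 (adjusted p = 0.00854, estimated 0.135), with PHGDH 81.6-fold lower and TRIB3 12.4-fold lower. Cholesterol genes had 9 of 26 higher and 4 lower (adjusted p = 0.0784), with INSIG1 3.64-fold higher, and the list was called at adjusted p = 0.0408 with limma-voom and 0.00248 with no filter on low counts (range 0.00248 to 0.138). Fatty acid genes had 6 of 22 higher and 2 lower (adjusted p = 0.0912), with ACSL4 5.002-fold higher, and this list was called at adjusted p = 0.0469 with limma-voom, 0.0095 with no filter on low counts, 0.0486 with only the compared lines fitted and 0.0233 without MCF10A replicate 1 (range 0.0095 to 0.153). NRF2 targets had 2 of 24 higher and 8 lower (adjusted p = 0.225): GSTP1 622-fold higher and NQO1 7.43-fold lower. Mitochondrially encoded mRNAs had a median of -0.25 with 13 of 13 not called (adjusted p = 0.634). Ribosomal protein genes had 2 of 53 higher and 2 lower (adjusted p = 0.707), with RPL8 3.42-fold lower. Cancer/testis genes had 6 of 7 higher and 1 lower (adjusted p = 0.103, median 7.58 or, with near-0 members at their bound, 5.16), with PAGE5 at least 127-fold higher, and the list was called at adjusted p = 0.0408 with limma-voom (range 0.0408 to 0.277). Leukocyte and endothelial markers had 1 of 8 higher and 5 lower (adjusted p = 0.382), with CD14 8.56-fold lower. SLC2A3 was 643-fold and GSTP1 5907-fold (95% interval 1497 to 44652) higher without HCC1937 replicate 7.

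For the genes named above as changed between the tumour lines the edgeR adjusted p lay between 1.47e-18 and 9.35e-08, and the CPM of the 4 MDA-MB-231 and the 4 HCC1937 libraries did not overlap. With an estimated correlation, camera kept 1 of the 12 lists called here, epidermal differentiation. Its call counts were 7 of 18 for HCC1937 against MCF10A and 6 of 19 for MDA-MB-231 against MCF10A.

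**Figure D2:**
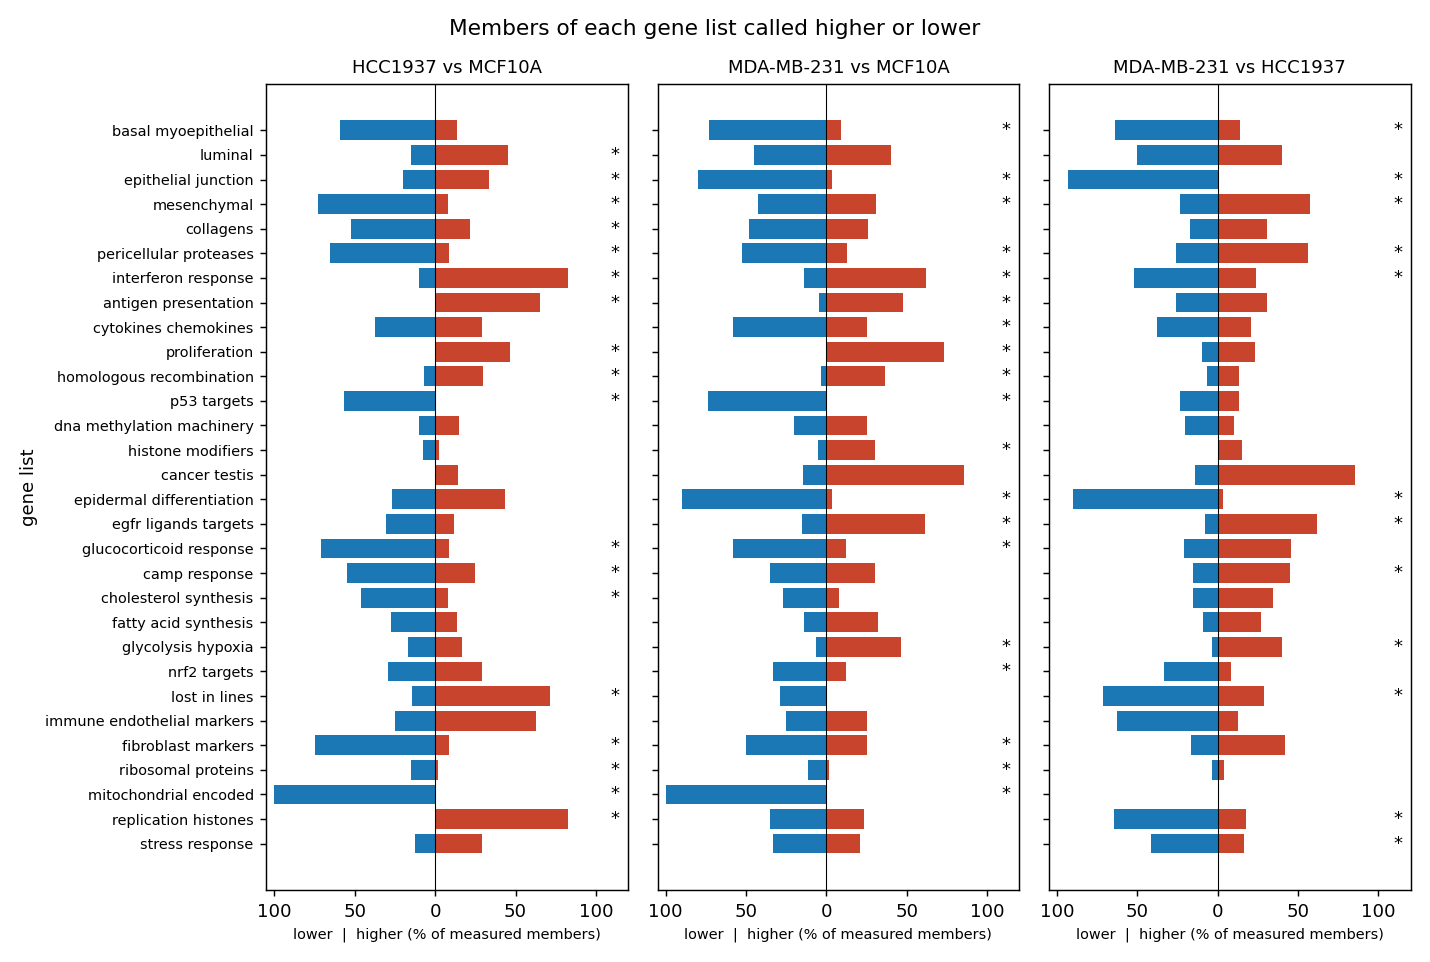
Share of the measured members of each of the 30 gene lists (percent) that were called higher or lower in each comparison, drawn as bars, with an asterisk where camera with a preset correlation gave an adjusted p under 0.05. Epidermal differentiation genes are mostly lower in MDA-MB-231 in both of its comparisons, and interferon-stimulated genes are mostly higher in both tumour lines than in MCF10A, with the directions taken after TMM scaling.

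Against MCF10A, 1549 genes were higher in both tumour lines and 1955 lower in both. Among the largest shared rises, PLIN2 stood at 93.4 ± 6.64 CPM in HCC1937 and 132 ± 5.25 CPM in MDA-MB-231 against 0.1603 ± 0.226 CPM in MCF10A. The largest shared falls included VCAN, FBN2, DCN, POSTN and CADM3 between 338 ± 56.7 CPM (POSTN) and 579.6 ± 94.4 CPM (VCAN) in MCF10A and at most 0.768 ± 0.535 CPM (VCAN in MDA-MB-231) in the tumour lines. Without MCF10A replicate 1 PLIN2 was 3023-fold (95% interval 564 to 124060) higher in HCC1937 and 4284-fold (799 to 175810) higher in MDA-MB-231.

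The other genes with the largest shared rises were COL5A1, CD74, CDH11, NIBAN1, CYBA, GSTM3, UCA1, GPX3 and AFAP1-AS1. GPX3, a secreted glutathione peroxidase, was 43.6-fold higher (205 ± 11.6 against 4.71 ± 2.32 CPM) in HCC1937 and 30.1-fold higher (142 ± 7.39 against 4.71 ± 2.32 CPM) in MDA-MB-231. The other shared falls were ROS1, IL1RL1, SLC6A15, ZBTB16 and FAP.

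Independent lists of these sizes among 17939 genes would share 770.3 higher and 898 lower genes, and 20 simulations of unchanged groups against the same controls shared 0 in either direction. The 3 MCF10A libraries are too few to split, so how much of the excess comes from the shared controls was not separated. Of the shared genes, 680 higher and 826 lower ones also differed between the tumour lines. In opposite directions, 615 genes were higher in HCC1937 and lower in MDA-MB-231, ESR1, EPCAM and KRT16 among them, against 976 for independent lists. The reverse held for 326 genes, VIM and ZEB1 among them, against 709.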

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

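The tests of this part, of a library far from the others of its line and of opposite changes in the tumour lines, were not chosen after their results were seen. Calls with 1 library left out were added afterwards. A library was taken as far from the others when its gap to the nearest, over the range of the line (its ratio), passed Dixon's 95% critical value, which chance does in about 1 of 20 groups. MCF10A, with 3 libraries, was not tested this way.

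In HCC1937 1 library stood apart in 12 of 233 named genes at 1 CPM or more, where chance would give about 11.65. The mitochondrial share of HCC1937 replicate 3 was 7.904% (Wilson 95% interval 7.893 to 7.915%, ratio 0.939), the highest of its line. Replicate 1 of HCC1937 lay apart in ATM 37.5 against 46.4 to 48.1 CPM (ratio 0.836), BMI1 37.4 against 26.4 to 27.4 CPM (ratio 0.904) and CCL5 14.3 against 12.5 to 12.8 CPM (ratio 0.842). It also lay apart in SPRY1 2.48 against 1.81 to 1.92 CPM (ratio 0.836). Replicate 3 of HCC1937 lay apart in AURKA 131 against 145 to 148 CPM (ratio 0.858), CXCL1 16.6 against 3.699 to 4.52 CPM (ratio 0.936) and DUSP4 41.9 against 31.7 to 32.4 CPM (ratio 0.933). It also lay apart in HSPA1A 49.4 against 61.7 to 63.1 CPM (ratio 0.897), MT-ND6 1053 against 666 to 711 CPM (ratio 0.883) and TNFRSF10B 69.9 against 50.5 to 52.2 CPM (ratio 0.912). So it did in VLDLR 4.58 against 3.604 to 3.69 CPM (ratio 0.909). Replicate 7 of HCC1937 lay apart in FANCI 36.99 against 30.1 to 31.1 CPM (ratio 0.866).

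In MDA-MB-231 this held for 10 of 208 genes, with about 10.4 by chance. Replicate 1 of MDA-MB-231 lay apart in COL8A1 250.5 against 257 to 258 CPM (ratio 0.93), CXCL8 7.47 against 9.09 to 9.31 CPM (ratio 0.881) and DNMT3B 12.8 against 9.86 to 10.3 CPM (ratio 0.847). It also lay apart in FAS 5.17 against 6.56 to 6.81 CPM (ratio 0.847) and KRT18 378 against 327 to 332 CPM (ratio 0.917). Replicate 2 of MDA-MB-231 lay apart in OASL 27.3 against 30.7 to 31.3 CPM (ratio 0.852). Replicate 3 of MDA-MB-231 lay apart in PHGDH 3.35 against 3.83 to 3.87 CPM (ratio 0.918). Replicate 4 of MDA-MB-231 lay apart in H1-4 1.86 against 1.31 to 1.39 CPM (ratio 0.854), IL11 58.4 against 51.6 to 52.3 CPM (ratio 0.897) and MT1E 79.99 against 48.7 to 52.6 CPM (ratio 0.875).

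The following named genes were called higher than MCF10A in HCC1937 and lower in MDA-MB-231. A call between the tumour lines was a condition for being listed and is not a further result. Their log2 fold changes of MDA-MB-231 against HCC1937 were VGLL1 -15.18 (at least 7222-fold), KLK5 -12.94, KLK6 -12.82, RARRES1 -12.81, KLHDC7B -12.68 (2679 to 37967), PKP1 -12.64 (1809 to 398160), KLK10 -12.40, KRT16 -12.08, PI3 -11.87, RAB25 -11.68 (1338 to 18954), LCN2 -11.45 and SPOCK2 -10.86. The next were ESRP1 -10.33, H2BC8 -10.17 (at least 224-fold), CALML5 -10.16 (408 to 12172), ELAVL2 -9.65 (228 to 50192), H3C8 -9.34 (at least 125-fold), H2BC9 -8.84 (at least 89.3-fold), KRT15 -8.29, FOXA1 -8.21, DMRTA1 -7.77 (at least 41.9-fold), ITGAM -7.48 (63.9 to 1905), ACTL8 -7.38 (at least 32.0-fold) and CXCL16 -6.92. The smallest were ESR1 -6.74, PHGDH -6.35, ELF3 -4.65, HLA-F -4.64, EPCAM -4.39 and OAS1 -3.90. The reverse, higher in MDA-MB-231 and lower in HCC1937, held for KLHL4 12.57 (2150.3 to 64141), CST1 12.42, EDIL3 11.95, ENPP1 10.07, PPARGC1A 9.85 (326 to 9736), SLC2A3 8.27, VIM 7.63, ZEB1 6.98 and PDE10A 5.70, and for SPRY1 5.12, ADAM8 5.08, DUSP6 4.97, PDGFRB 4.91, DUSP4 4.64, MCAM 4.08, STARD4 2.60 and ACSL4 2.32. Where a gene had 0 counts in the lower line the bound on its fold stands in parentheses, with 1 to 3 counts the 95% counting interval of the fold, and these hold in place of the fitted value and its rank. Without 1 library some folds moved by over 1.5 times: KRT16 7466, ITGAM at least 116, ELAVL2 at least 318 without MDA-MB-231 replicate 2, PKP1 at least 2559 without MDA-MB-231 replicate 4, CALML5 2677 (418 to 91881), PI3 7866 without MDA-MB-231 replicate 3, SLC2A3 643 without HCC1937 replicate 7, CST1 9699.6 (2745 to 81882), EDIL3 6947 (2347 to 33265), KLHL4 12073 (2215 to 487500) without HCC1937 replicate 3 and PPARGC1A at least 592 without HCC1937 replicate 1.

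Against MCF10A the CPM of the libraries overlapped for KLHDC7B, VGLL1, ACTL8 and CALML5 in MDA-MB-231 and for CST1 and EDIL3 in HCC1937. The opposite change of 4 genes rested on 1 MCF10A library: without replicate 1 MCF10A had 1 count of CST1 and 0 of EDIL3 and VGLL1, and without replicate 3 0 of ACTL8, so no direction against it was left. Other calls against MCF10A were lost when 1 library was left out. CST1 in HCC1937 had adjusted p = 0.0893 and 0.0934 without HCC1937 replicates 1 and 7 and 0.0504 without MDA-MB-231 replicate 1. EDIL3 in HCC1937 had adjusted p = 0.0732, 0.0703 and 0.0507 without HCC1937 replicates 1, 7 and 8. DMRTA1 in HCC1937 had adjusted p = 0.0675 and 0.0658 without HCC1937 replicates 1 and 7 and 0.0954 and 0.0722 without MCF10A replicates 1 and 3. ACSL4 in MDA-MB-231 had a log2 fold change of 0.996, 0.995 and 0.996 without HCC1937 replicates 1, 7 and 8, 0.98 and 0.99 without MDA-MB-231 replicates 2 and 3 and 0.99 without MCF10A replicate 3. KLHDC7B in MDA-MB-231 had adjusted p = 0.0641, 0.0829 and 0.0519 without MDA-MB-231 replicates 1, 2 and 4 and 0.414 and 0.0834 without MCF10A replicates 1 and 4. MCAM in MDA-MB-231 had a log2 fold change of 0.997 and 0.9997 without MDA-MB-231 replicates 1 and 4 and 0.93 without MCF10A replicate 3. ELAVL2 in HCC1937 had a log2 fold change of 0.80 without MCF10A replicate 1. PDE10A in HCC1937 had a log2 fold change of -0.98 without MCF10A replicate 4.

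The epithelial junction list was called higher in HCC1937 and lower in MDA-MB-231 than MCF10A, with a median of -4.07 between the tumour lines. With an estimated correlation these calls and that between the tumour lines were lost (adjusted p = 0.657, 0.258 and 0.255). The call in HCC1937 was also lost with limma-voom (adjusted p = 0.209) and without MCF10A replicate 1 (adjusted p = 0.778, range over its alternatives 0.00773 to 0.778).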

How the results depend on the processing

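The alternatives of this part were fixed beforehand. Over the named genes and their alternatives, 9347 values lay on the same side of the test in the same direction, 25 passed it newly, 27 passed it no longer and 13 changed sign, those of ERBB2 and TET2. In runs added after the results were seen the calls of CST1 and EDIL3 in HCC1937 were lost (adjusted p = 0.938 and 0.11) without MCF10A replicate 1. For the 49 lists called, 987 values were the same and 89 were weaker.

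The fold minimum set the counts most. With no minimum there were 6863 higher and 6575 lower in HCC1937 against MCF10A, 6620 and 6474 in MDA-MB-231 against MCF10A, 6864 and 7203 in MDA-MB-231 against HCC1937, and 3679 and 3697 in both tumour lines. With a log2 minimum of 2 there were 2350 higher and 1841 lower in HCC1937 against MCF10A, 1672 and 2486 in MDA-MB-231 against MCF10A, 1687 and 2834 in MDA-MB-231 against HCC1937, and 815 and 819 in both tumour lines. These alternatives change the threshold itself, which is the cause. With an estimated correlation camera called 7, 6 and 1 lists in the same order of comparisons, and fry called 29 in HCC1937 against MCF10A and 28 in MDA-MB-231 against HCC1937. The cause of these differences was not tested. DESeq2 gives no list test and was not planned for lists.

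Leaving out each library in turn gave 3934 to 4490 genes higher and 3674 to 3762 lower in HCC1937 against MCF10A. The ranges were 3253 to 3684 and 4139 to 4275 in MDA-MB-231 against MCF10A, 3528 to 3700 and 4473 to 5072 in MDA-MB-231 against HCC1937, and 1494 to 1716 and 1907 to 1989 in both tumour lines. Lists called ranged over 16 to 18, 18 to 21 and 11 to 12. MCF10A replicate 1 decided the epithelial junction call in HCC1937, whose adjusted p was 0.778 without it (range over its alternatives 0.00773 to 0.778). With the replicate number as a block the counts were 3782 higher and 3375 lower in HCC1937 against MCF10A, 3225 and 3935 in MDA-MB-231 against MCF10A, 3422 and 4220 in MDA-MB-231 against HCC1937, and 1403 and 1667 in both tumour lines, with 16, 14 and 12 lists. Same-numbered libraries of different lines did not vary together (r across 11202 genes from -0.066 to 0.185), and genes are not independent replicates.

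ERBB2 in HCC1937 against MCF10A was -0.26 and 0.0278 with library totals alone (log2). TET2 in HCC1937 against MCF10A was -0.01 and 0.0366 with DESeq2, 0.0284 with RLE size factors, 0.0653 with upper-quartile scaling, 0.28 with library totals alone, 0.0806 with no filter on low counts, 0.00729 with a filter of 1 CPM in 3 libraries, 0.02097 with only the compared lines fitted, 0.0207 and 0.0579 without HCC1937 replicates 1 and 3 and 0.0956 and 0.0199 without MCF10A replicates 1 and 3, and in MDA-MB-231 against HCC1937 it was -0.11 and 0.0215 with the replicate block. Over the libraries left out in turn, TET2 in HCC1937 against MCF10A ran from -0.0378 to 0.0956. The cause was not tested.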

Other observations

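The splits of the libraries, the shuffles of silent genes and the tests of explanations in this part were chosen after the results were seen. Segments of neighbouring genes were silent (off), each at a mean under 0.2 CPM in a line where another had 1 CPM or more. In MDA-MB-231 the epidermal differentiation genes from CRCT1 to S100A7 were off (chromosome 1, 152514482 to 153460651, 13 genes, 29 counts), with SPRR1B at 79.3 CPM in MCF10A, 16.4 in HCC1937 and 0.0271 in MDA-MB-231. Kallikreins from KLK6 to KLK14 were off (chromosome 19, 50958631 to 51084245, 7 genes, 40 counts), with KLK7 at 137 CPM in MCF10A, 368 in HCC1937 and 0.0837 in MDA-MB-231. Runs as long as each arose in 0 of 1000 shuffles of the off genes over gene positions. In HCC1937 the cystatins from CST3 to CST7 were off (chromosome 20, 23626706 to 24959928, 5 genes, 27 counts, 5 of 1000 shuffles), with CST3 at 276 CPM in MCF10A, 0.104 in HCC1937 and 384 in MDA-MB-231, while CST4, CST1, CST2 and CST7 were low in MCF10A too (0.0798, 0.2402, 0.0399 and 0.0382 CPM). In MDA-MB-231 the genes from HACD4 to ELAVL2, which include CDKN2A, were off (chromosome 9, 20999509 to 23826337, 7 genes, 8 counts, 0 of 1000 shuffles), while the non-coding CDKN2B-AS1 kept 1.72 CPM against 11.8 CPM.

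MCF10A replicate 1 was lower than replicates 3 and 4 in epithelial junction genes. MDA-MB-231 RNA is argued against as the cause, not as a trace. The 12 genes abundant there and near 0 in replicates 3 and 4 had a median of 0.345% of their MDA-MB-231 level (75th percentile 0.431%), where 55.3% would be needed. A library of another line is argued against by 18 genes expressed in MCF10A alone, whose median ratio to replicates 3 and 4 was 1.30. Depth is argued against by a total of 18372374 counts, above the 17859926 of replicate 3. No biological explanation was tested, and a difference in the state of the culture stays open.

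Glucocorticoid-responsive genes were lower in both tumour lines than in MCF10A, whose medium alone held hydrocortisone. Scaling of the libraries is argued against as the whole cause, since the list's median nearest to 0 over the other scalings was -1.47. Over 24 genes the median nearer to 0 of the tumour lines was -1.76, which restates the fall and does not test hydrocortisone. Line and medium cannot be told apart because each line had its own medium, so hydrocortisone stays open. Between the tumour lines, whose media name no hydrocortisone, the median was 0.75 (adjusted p = 0.463).

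The numbers of genes and lists called between the lines were set against other splits of the libraries, in fits of the 2 lines compared. For HCC1937 against MCF10A the real split called 7297 genes and the highest of the others 0, 1 of 35 splits being as large. For MDA-MB-231 against MCF10A these were 6873 and 0, and for MDA-MB-231 against HCC1937 7685 and 0 (1 of 35 each), beyond what random splits gave. For the lists called, the real split gave 17 in HCC1937 against MCF10A (2 of 35 as large, others up to 17, median 13.5). It gave 19 in MDA-MB-231 against MCF10A (1 of 35, others up to 18, median 11) and 11 between the tumour lines (1 of 35, others up to 9, median 3). Splits that mix the lines call many lists too, so these counts leave chance open for the lists. For the 1549 genes higher and 1955 lower in both tumour lines 1 of 100 splits was as large. The rest mixed lines and shared 0, which does not test the overlap.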
